A study of Mus musculus with 16 samples.

How the data were processed

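Deletions at 1 hotspot of meiotic recombination on mouse chromosome 1 were measured by deep sequencing of PCR products. A hotspot is a short stretch of the genome in which SPO11, the enzyme that makes the DNA double-strand breaks of meiosis, cuts often. DNA came from testicular cell suspensions of adult C57BL/6 mice aged 2 to 5 months, and the labels give spermatocytes as the cell type. The genotypes were Atm-/- (without ATM, the kinase that responds to breaks and restrains SPO11), Atm+/-, Atm+/+ and Spo11-/- (without meiotic breaks). For each of the 4 genotypes, 4 overlapping amplicons of about 580 bp were made with 22 cycles of PCR, which gave 16 libraries, 1 per genotype and amplicon. Per the labels' protocols, the whole suspension was used for mutant testes and only part of it for wild-type testes. The number of animals and the number of genomes put into each PCR are not given in the sources used here. The p-values therefore measure only the spread between libraries, which may be technical.

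Each file lists the distinct aligned read sequences of 1 library that hold exactly 1 deletion. The deposited counts are whole numbers of reads per distinct aligned sequence, with no normalization, per the file headers. The deposited percent column gives each sequence's reads as a percent of all reads of the library. Dividing the first by the second gave 1 total per library, and this total served as the depth. The file headers follow the column layout of CRISPResso, a program that aligns amplicon reads and tabulates insertions and deletions; its version and settings are not given in the sources used here. The genome build is mm10, per the submitters' processing notes. Each row also holds the number of deleted and substituted bases and the chromosome position of the first deleted base. The listed deletions were 2 to 229 bp long, no inserted base was listed, and deletions of 1 bp were not analysed here. Coordinates are printed as the files give them, and whether the files count chromosome positions from 0 or from 1 could not be checked without a genome sequence. The gene annotation used was for the same build, without exons.

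The 16 files held 73567 rows, of which 25 were left out because the aligned sequence was not as long as the amplicon. The amplicon sequence was rebuilt from the most frequent base at each position over the listed sequences, each counted once whatever its reads. This base made up at least 93.3% of the determined bases at every position more than 20 bp from the amplicon's ends. A deletion that could be placed at several positions without changing the product was moved to its left-most placement, and the number of positions it could be moved by was taken as the length of microhomology, the short repeat shared by both ends. Deletions with the same left-most start and the same length in a library were counted as 1 distinct deletion. Deletions that differed by even 1 base in start or length were counted apart, also where they could be altered copies of 1 molecule. The number of distinct deletions of 11 bp or more per 1e6 reads was the first measure, since exact PCR copies add reads but no distinct deletions. Reads with such a deletion per 1e6 reads, distinct deletions of 2 to 10 bp, the median length and the percent with at least 2 bp of microhomology were the others. The comparison of the shorter class was fixed for 1 to 10 bp before the files were seen and was run on 2 to 10 bp. The percent of microhomology expected by chance was computed by placing deletions of the same lengths at every possible position of the same amplicon.

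Depth was 2.92 to 5.33 in units of 1e6 reads per library. Rates were compared as log2 of the count plus 0.5 per 1e6 reads. Amplicon was kept as a block in every main test, because the 4 genotypes share the 4 amplicons by design: genotypes were exchanged only within an amplicon. Atm-/- was compared with the other 3 genotypes over all 256 assignments of 1 library per amplicon, in a two-sided exact permutation test whose smallest p is 0.0039. Spo11-/- was compared with Atm+/+ and Atm+/- over 81 assignments, with a smallest p of 0.0123 in the exact test. Pairs of genotypes were compared over 16 sign patterns, and that exact test cannot reach 0.05. The 5 length classes were adjusted together by the Benjamini-Hochberg method. Intervals on percentages are exact Clopper-Pearson intervals at 95%, and intervals on counts are exact Poisson intervals at 95%. PCR reads carry no molecular identifiers here, so these intervals cover counting error only.

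The deletions named in the text follow a rule fixed before the data were examined. It takes, in each amplicon, the 3 deletions with the most reads that only the Atm-/- library holds, and the 1 deletion with the most reads in the other 3 genotypes. For each genotype it also takes the 5 deletions with the most reads among those found in 2 or more of its amplicons. The 50-bp windows with the highest and the lowest ratio of Atm-/- to the mean of the other 3 genotypes are named too. The rule was applied to all reads and again to reads without substitutions.

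Alternatives fixed before the data were examined were other minimum lengths of 5, 20 and 30 bp, at least 2 or 5 reads per deletion, deletions private to 1 library, thinning to the smallest library of the amplicon, only reads without substitutions, the deposited placement, a pseudocount of 1, other minimum lengths of microhomology, no replicate block, each amplicon left out, and the submission set as a further block. Further alternatives were chosen after seeing the data: leaving out reads with an undetermined base, leaving out in addition to reads with substitutions every deletion with an end in a 41-bp stretch at the middle of the amplicon, and leaving out the second submission set with and without the reads with substitutions.

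The submission sets come from the library names in the labels, which fall into 4 sets of 4 libraries. The first set is the 4 Atm-/- libraries. The second set is Atm+/+ amplicons 1 and 2 with Atm+/- amplicons 3 and 4. The third set is Spo11-/- amplicons 1 and 2 with Atm+/+ amplicons 3 and 4, and the fourth set is Atm+/- amplicons 1 and 2 with Spo11-/- amplicons 3 and 4.

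The 50-bp windows covered by 3 or 4 amplicons were tested in the same way, with Benjamini-Hochberg adjustment over 8 windows, a test added after seeing the data.

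The permutation test was tested on simulated libraries with the real depths. It called 3.5% of 200 draws without a difference, 88.5% of 200 draws with a 2-fold difference and 100% of 200 draws with a 4-fold difference. Counts were Poisson draws at 1 rate per amplicon, set from the other 3 genotypes in reads without substitutions. No difference between submission sets and no further spread between libraries was simulated. These shares therefore do not describe the test where sets differ, as they did over all reads. The placement step returned the left-most start and the microhomology of 2000 of 2000 simulated deletions. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.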

Results

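The 16 libraries covered chromosome 1 from 33764688 to 33765556 (mm10), a stretch of 869 bp inside the protein-coding gene Zfp451 (gene ID 98403, 33761541 to 33815602), a zinc finger gene. Whether the stretch is exonic or intronic was not analysed here. Amplicon 1 spanned 33764688 to 33765262, amplicon 2 33764797 to 33765375, amplicon 3 33764915 to 33765491 and amplicon 4 33764983 to 33765556. Depth, in units of 1e6 reads and for amplicons 1 to 4, was 3.61, 3.07, 3.71 and 3.24 in Atm-/-, 3.62, 4.04, 5.33 and 4.70 in Atm+/-, 5.10, 4.40, 3.36 and 3.25 in Atm+/+, and 3.34, 2.92, 4.49 and 3.57 in Spo11-/-. At these depths 1 distinct deletion in a library corresponded to 0.187 to 0.343 per 1e6 reads.

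The first comparison asked whether loss of ATM changes the number of deletions at the hotspot. Atm-/- libraries held more distinct deletions of 11 bp or more than every library of the other 3 genotypes. They held 34.8 ± 4.52 per 1e6 reads (SD, n = 4), against 9.43 ± 5.77 in Atm+/-, 9.37 ± 8.24 in Atm+/+ and 2.95 ± 1.25 in Spo11-/-. In counts, 472 distinct deletions were found in Atm-/-, 179 in Atm+/-, 168 in Atm+/+ and 42 in Spo11-/-. The difference between Atm-/- and the other 3 genotypes was 6.51-fold (log2 2.70), and 5.86-fold to 7.56-fold in single amplicons. This is a difference of mean log2 values and not the ratio of mean rates. The mean rate over the other 12 libraries was 7.25 per 1e6 reads. Atm-/- was the highest in 4 of 4 amplicons (exact permutation test, p = 0.0039). This p is the smallest the design can give. The fold was 4.05 without reads that hold an undetermined base, 10.97 without the second submission set and 12.2 with at least 2 reads per deletion, and the call held in each. Against Atm+/+ alone the difference was 5.30-fold and against Spo11-/- alone 12.2-fold, and each had the smallest exact permutation p that 4 pairs allow, which does not reach 0.05. The fold against Spo11-/- was 7.64 in reads without substitutions, 5.58 with ends in the middle of the amplicon also left out, and 34.4 with at least 2 reads per deletion. Counted in reads, deletions of 11 bp or more made up 99.5 ± 13.8 per 1e6 reads in Atm-/- (SD, n = 4), against 20.4 ± 16.7 in Atm+/-, 59.5 ± 76.8 in Atm+/+ and 3.92 ± 2.19 in Spo11-/-. The difference of mean log2 values was 3.31, or 9.89-fold (exact permutation p = 0.0156). It is not a ratio of these means, and in total 1363 reads in Atm-/- stood against 1533 in the other 12 libraries. In this count 1 Atm+/+ library, amplicon 2, lay above the Atm-/- library. Leaving out amplicon 3 or amplicon 4 ended the call on reads (exact permutation p = 0.0625 for each, over 64 assignments), with folds of 9.46 and 9.64. Leaving out reads with an undetermined base lowered the fold to 4.00 (exact permutation p = 0.0977). The fold was 24.2 without the second submission set and 33.9 with at least 5 reads per deletion, and the call held in both.

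Much of the count in Atm-/- and in the second submission set lay in reads of a particular kind. In Atm-/-, 61.1% of the 1363 reads with a deletion of 11 bp or more held an undetermined base. Of the same reads, 74.7% had an end of the deletion in a 41-bp stretch at the middle of the amplicon. In the second submission set (Atm+/+ amplicons 1 and 2, Atm+/- amplicons 3 and 4), 16.9% of 1406 such reads held an undetermined base and 92.2% had an end in that stretch. In the third and the fourth set the shares with an end there were 8.70% of 46 reads and 9.88% of 81 reads. None of these reads held an undetermined base. Of the reads with an undetermined base, 833 of 833 in Atm-/- and 237 of 238 in the second set had an end in the stretch. Among reads without substitutions the shares were 33.6% in Atm-/-, 70.9% in the second set and 9.80% in the third and the fourth set together. Within the other 3 genotypes, libraries of the second set had 4.78-fold more distinct deletions than those of the third and the fourth set (exact permutation p = 0.0123, the smallest possible). All Spo11-/- libraries are in the third and the fourth set, so this fold mixes submission set with genotype. The 4 Atm-/- libraries form the first set by themselves, so genotype and submission set cannot be told apart for them.

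**Figure D1:**
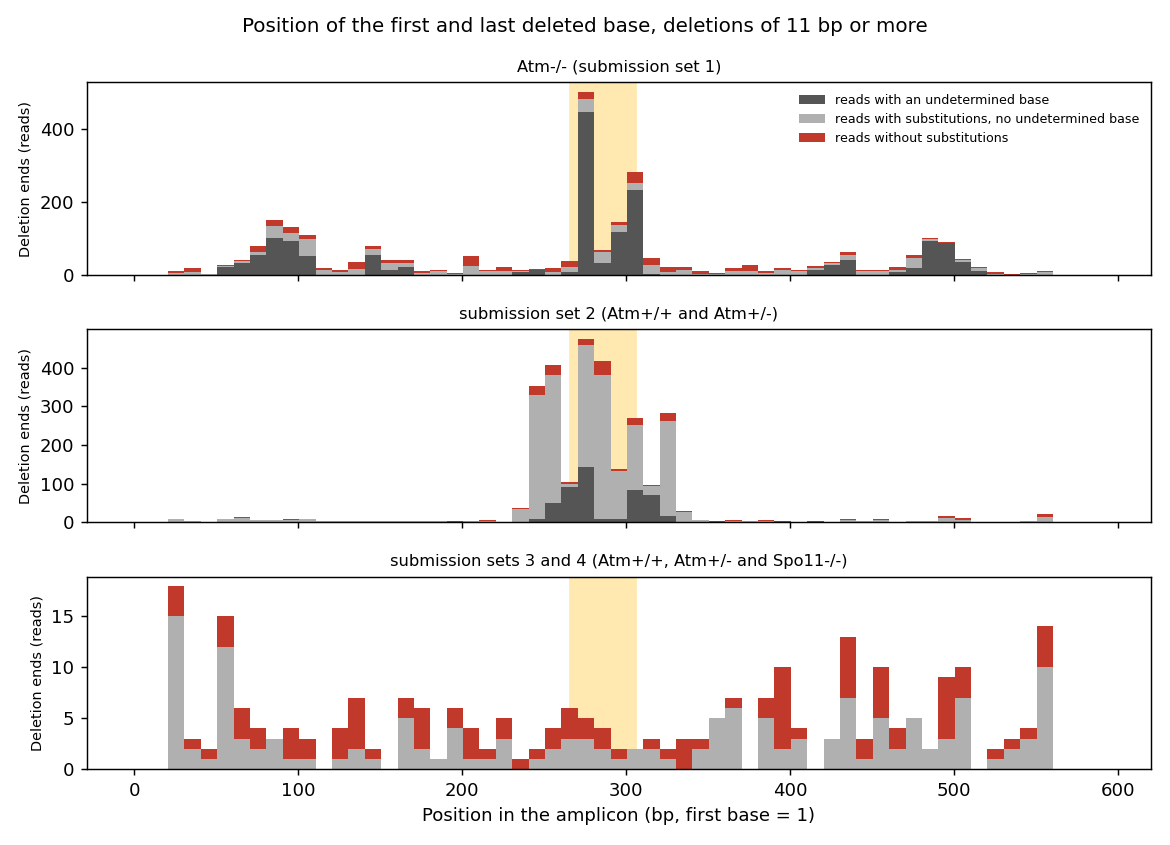
Position in the amplicon (bp) of the first and last deleted base of deletions of 11 bp or more, in 10-bp bins, as reads (vertical axis, with a different scale in each panel), by submission set. Colours separate reads with an undetermined base, other reads with substitutions and reads without substitutions, and the shaded band is the 41-bp stretch at the middle of the amplicon. In Atm-/- and the second set 74.7% and 92.2% of these reads have an end in the band, against 8.70% and 9.88% in the third and the fourth set.

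In reads without substitutions, an alternative fixed before the data were examined, Atm-/- had 150 distinct deletions of 11 bp or more, against 37 in Atm+/-, 28 in Atm+/+ and 23 in Spo11-/-. Per 1e6 reads these were 11.03 ± 1.58 in Atm-/-, 2.01 ± 0.82 in Atm+/-, 1.68 ± 0.72 in Atm+/+ and 1.64 ± 1.04 in Spo11-/- (SD, n = 4 each). Atm-/- was 6.49-fold higher than the other 3 genotypes and the highest in 4 of 4 amplicons (exact permutation p = 0.0039). Its lowest library held 9.57 distinct deletions per 1e6 reads, and the highest of the other 12 libraries 3.00. Reads with such a deletion were 6.79-fold more frequent (exact permutation p = 0.0039). With deletions ending in the middle of the amplicon also left out, a setting chosen after seeing the data, 106 distinct deletions in Atm-/- stood against 63 in the other 3 genotypes together, a 6.08-fold difference per 1e6 reads (exact permutation p = 0.0039).

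**Figure D2:**
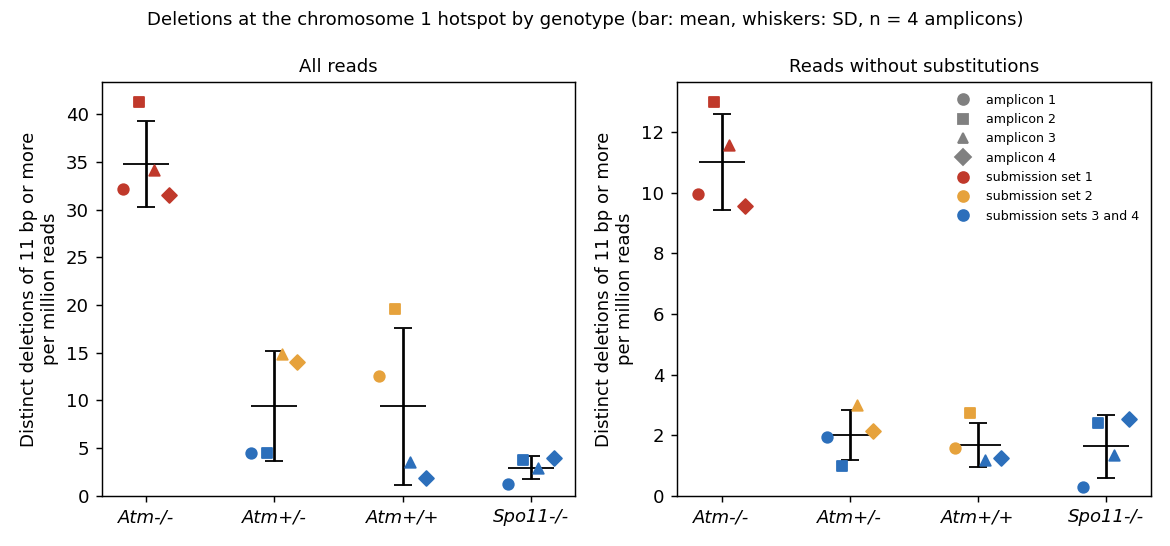
Distinct deletions of 11 bp or more per 1e6 reads (vertical axis, from 0) by genotype, for all reads on the left and reads without substitutions on the right. Each point is 1 amplicon's library, coloured by submission set, with the mean and SD over 4 amplicons. The 4 Atm-/- libraries lie between 31.5 and 41.3 on the left and between 9.57 and 13.0 on the right, above all libraries of the other 3 genotypes in both panels.

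By length, the Atm-/- excess over all reads was found in deletions of 30 bp or more. In reads without substitutions it reached down to 11 bp. Deletions of 2 to 10 bp showed no excess in either. Deletions of 100 bp or more were 16.6-fold and those of 30 to 99 bp 4.87-fold more frequent in Atm-/- than in the other 3 genotypes, with Atm-/- highest in 4 of 4 amplicons (exact permutation p = 0.0039, adjusted p = 0.00977 over 5 classes for each). In reads without substitutions the folds were 8.0 for 100 bp or more, 6.10 for 30 to 99 bp (both with the same exact permutation p) and 4.21 for 11 to 29 bp (exact permutation p = 0.0117, adjusted p = 0.0195). With ends in the middle of the amplicon also left out the folds were 5.19, 6.29 and 5.09 in the same order, with no rise with length. The longest listed deletion was 228 or 229 bp in every Atm-/- library. Whether longer ones could be listed was not checked, so classes and medians describe listed lengths only. The class of 11 to 29 bp was 2.82-fold higher over all reads, without passing the test (exact permutation p = 0.184, adjusted p = 0.306). Atm-/- was highest there in 0 of 4 amplicons. Its mean was 5.25 distinct per 1e6 reads, against 5.07 in Atm+/+, 3.94 in Atm+/- and 0.76 in Spo11-/-. Deletions of 2 to 10 bp, which PCR and sequencing errors also make, served as a measured background. They numbered 75.9 ± 1.93 distinct per 1e6 reads in Atm-/- and 79.9 ± 9.05 in the other 12 libraries (SD), a log2 difference of -0.06 (exact permutation p = 0.488). In reads without substitutions this class was lower in Atm-/-, by a log2 difference of -0.23 (exact permutation p = 0.043). With ends in the middle of the amplicon also left out the difference was again -0.23 and did not pass the test (exact permutation p = 0.0547).

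Over all reads the deletions of 11 bp or more were longer in Atm-/-, with a median of 122 ± 8.15 bp (SD, n = 4) against 46.8 ± 23.4 bp in the other 12 libraries, a difference of 75.4 bp (exact permutation p = 0.0039). This difference was not found in reads without substitutions, where the median was 74.8 ± 10.51 bp in Atm-/- and 70.8 ± 44.1 bp in the others (difference 3.92 bp, exact permutation p = 0.918). With deletions ending in the middle of the amplicon also left out it turned to -20.9 bp (exact permutation p = 0.363).

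Microhomology of at least 2 bp was present at 29.6% ± 4.49 of distinct deletions in Atm-/- and 41.4% ± 19.0 in the other 12 libraries over all reads (SD), a difference of -11.8 percentage points that did not pass the test (exact permutation p = 0.293). The values in reads without substitutions were 39.3% ± 3.91 and 61.3% ± 18.4, and the difference of -22.0 points passed it (exact permutation p = 0.0391). With the second submission set also left out it was -26.3 points and did not pass the test (exact permutation p = 0.0741 over 81 assignments). Leaving out deletions seen in more than 1 genotype of the amplicon, over all reads, turned the difference to 0.28 points (exact permutation p = 0.996). Libraries weigh equally in these means, including a Spo11-/- library with 1 deletion in reads without substitutions. Pooled over libraries, 59 of 150 Atm-/- deletions in these reads had at least 2 bp (39.3%, 95% Clopper-Pearson interval 31.5 to 47.6), where random placement gave 17.2%. In the other 3 genotypes 49 of 88 had it (55.7%, interval 44.7 to 66.3), where random placement gave 17.4%. Microhomology of at least 4 bp was found at 12.7% of the Atm-/- deletions (interval 7.80 to 19.1) and 37.5% of the others (interval 27.4 to 48.5). In these pooled values a deletion found in several libraries counts once in each, so the intervals can be too narrow. In Atm+/+, 33765045 to 33765075 (8 bp of microhomology) counts in amplicons 1, 2, 3 and 4. Shares with each deletion counted once were not computed.

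Along the hotspot, the Atm-/- deletions in reads without substitutions were densest around the centre of the stretch. Both ends of a deletion must lie inside the amplicon, so windows near an amplicon's end can be overlapped by fewer deletions in any genotype. The window with the highest ratio to the mean of the other 3 genotypes was 33764988 to 33765037, where 63 distinct Atm-/- deletions gave 6.06 per 1e6 reads (95% Poisson interval 4.66 to 7.75) and the others 0.45, a ratio of 13.3. The neighbouring window 33765038 to 33765087 held the most Atm-/- deletions, 89 or 6.53 per 1e6 reads (interval 5.24 to 8.03), at a ratio of 11.2. The lowest ratio, 3.06, was at 33764838 to 33764887, with 9 Atm-/- deletions or 1.35 per 1e6 reads (interval 0.62 to 2.56). Over all reads the highest ratio was 17.9 at 33764788 to 33764837, a window covered by amplicon 1 alone, and the lowest 5.17 at 33764938 to 33764987. The ratio at 33764788 to 33764837 was 6.48 in reads without substitutions. With ends in the middle of the amplicon also left out it was 1.62, from 2 Atm-/- deletions. A test of the 8 windows that 3 or 4 amplicons cover, added after the data were examined, found Atm-/- higher in 8 of 8 in reads without substitutions. The folds ran from 3.29 to 12.8 (exact permutation p from 0.0039 to 0.0469, adjusted p at most 0.0469 over 8 windows). A deletion counts in every window it overlaps, so the windows share deletions and are not separate tests of the excess. With ends in the middle of the amplicon also left out, 5 of 8 passed after adjustment. Windows covered by 1 or 2 amplicons were not tested.

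**Figure D3:**
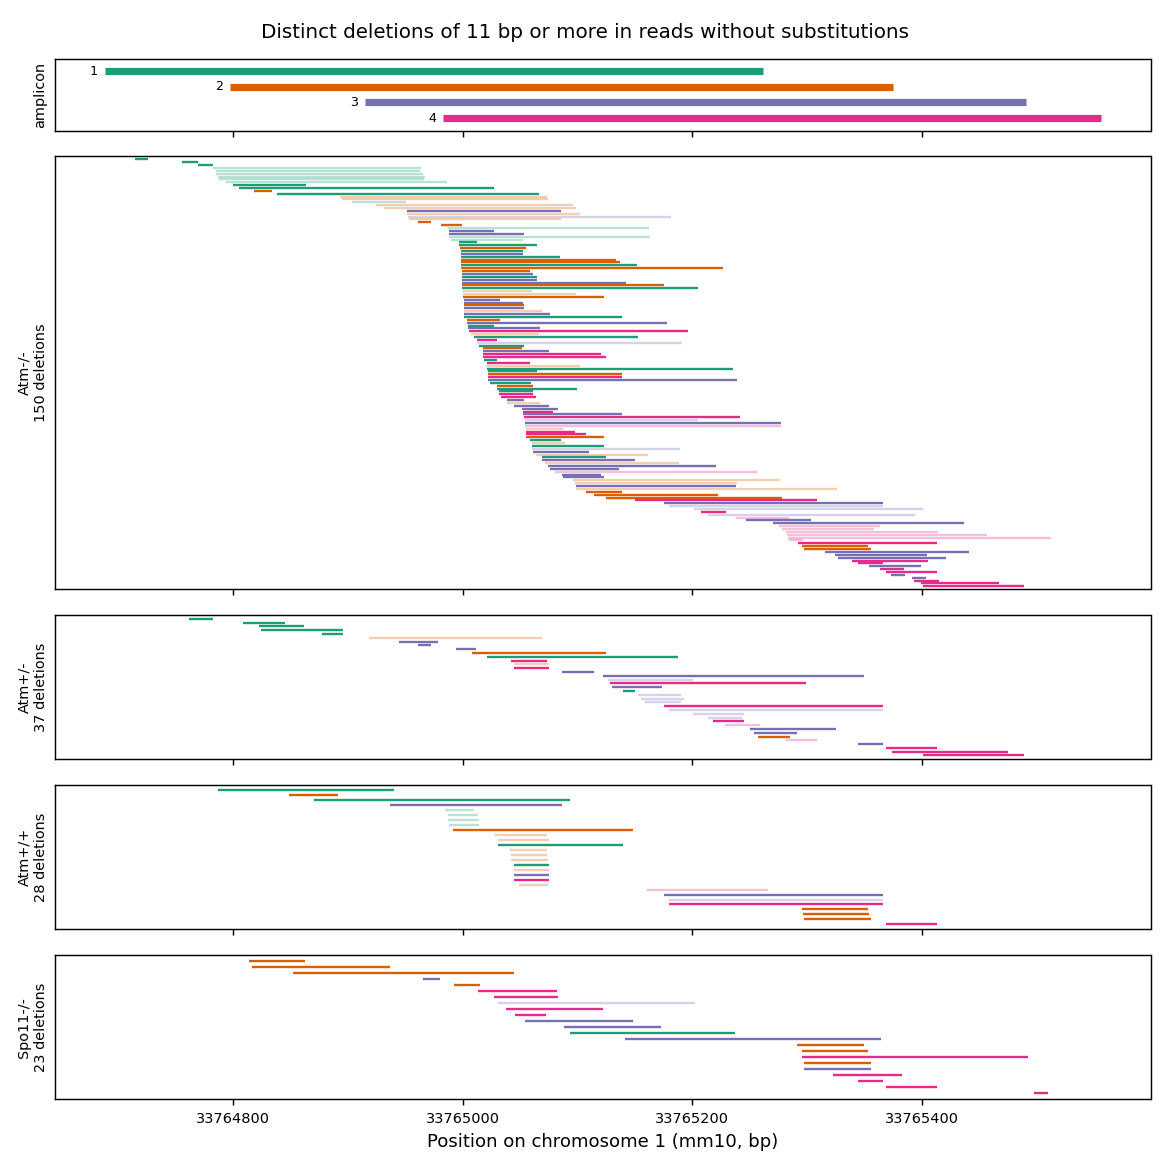
Distinct deletions of 11 bp or more in reads without substitutions along chromosome 1 (mm10, bp), 1 line per deletion from its first to its last deleted base, coloured by amplicon and in 1 panel per genotype, under the extents of the 4 amplicons. Pale lines have an end in the 41-bp stretch at the middle of the amplicon. The window from 33765038 to 33765087 holds 89 of the 150 Atm-/- deletions, 14 of the 28 of Atm+/+, and 7 each of the 37 of Atm+/- and the 23 of Spo11-/-.

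Among single deletions, the 12 with the most reads that only an Atm-/- library held were 128 to 209 bp long, had 11 to 75 reads each over all reads, and had an end in the middle of the amplicon without exception. The one with the most reads, 33764783 to 33764963 in amplicon 1 (181 bp, 3 bp of microhomology), had 75 reads with a median of 5 substitutions per read, of which 6 reads were free of substitutions. The named Atm-/- deletions in reads without substitutions had 2 to 6 reads each. Of those that only the Atm-/- library of an amplicon held, the ones with 5 or 6 reads all had an end in the middle of the amplicon. Those without such an end included 33765054 to 33765241 in amplicon 4 (188 bp, no microhomology, 4 reads) and 33764839 to 33765066 in amplicon 1 (228 bp, 1 bp of microhomology, 3 reads). Over all reads, 18 distinct deletions were found in 2 or more amplicons of Atm-/-, against 4 in Atm+/-, 5 in Atm+/+ and 1 in Spo11-/-. The totals summed over amplicons were 472, 179, 168 and 42 in the same order. In reads without substitutions 6, 1, 2 and 1 were found in 2 or more amplicons, beside totals of 150, 37, 28 and 23. Atm-/- thus also had the most deletions in total, and whether recurrence differs beyond the totals was not tested. Among the Atm-/- deletions found in 2 or more amplicons over all reads, 33765002 to 33765053 (52 bp, 1 bp of microhomology) had the most reads. It had 11 reads in amplicons 1, 2 and 3 and none in another genotype. Next to it, 33765000 to 33765064 (65 bp, no microhomology) had 5 reads in amplicons 1 and 3, and 33765001 to 33765123 (123 bp, 2 bp) had 5 reads in amplicons 1, 2 and 3, again with none in another genotype. The other 2 named for Atm-/- have an end in the middle of at least 1 of their amplicons. Of these, 33765055 to 33765277 (223 bp) had 6 reads and was in no other genotype. The other, 33765043 to 33765074 (32 bp), had 5 reads with a median of 34 substitutions and was also found in Atm+/+. In Atm+/+ the deletion 33765045 to 33765075 (31 bp, 8 bp of microhomology) was found in 4 of 4 amplicons with 221 reads, 218 of them in amplicon 2, and was also found in Atm+/- and Atm-/-. It had the most reads of the other 3 genotypes in amplicon 2. In amplicon 1 this was 33764989 to 33765014 (26 bp), with 96 reads in Atm+/+. In amplicons 3 and 4 these were 33765160 to 33765193 and 33765242 to 33765255, with 23 reads each in Atm+/-. All had an end in the middle of the amplicon.

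The second comparison asked whether deletions at the hotspot in animals with ATM exceed those in animals without meiotic breaks. Spo11-/- libraries were compared with Atm+/+ and Atm+/- libraries in distinct deletions of 11 bp or more. The log2 difference of -1.36 did not pass the test (exact permutation p = 0.148), and neither did that of -2.28 in reads with one (exact permutation p = 0.136). With the submission set as a further block these moved to -0.31 (exact permutation p = 0.397) and -0.46 (exact permutation p = 0.487). The difference in distinct deletions was -0.35 in reads without substitutions (exact permutation p = 0.556), and with ends in the middle of the amplicon also left out it was 0.18 (exact permutation p = 0.741). These 12 libraries held 1 to 16 distinct deletions each in reads without substitutions.

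The third comparison, of 1 lost copy of Atm with none, gave a log2 difference of 0.31 in distinct deletions of 11 bp or more between Atm+/- and Atm+/+ (exact permutation p = 0.875). It was 0.22 in reads without substitutions (exact permutation p = 0.75). For this pair each genotype has 2 amplicons in the second submission set, and with the set as a further block the difference was -0.03 (exact permutation p = 1). That fit also used the Spo11-/- libraries, with a term of their own, because set and genotype cannot be separated within the pair alone.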

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

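The tests of explanations in this part were chosen after the result each one bears on was seen. Chance puts about 1 in 20 groups past the limit used for single libraries that stand apart, and 1 of the 20 groups tested did so. In Spo11-/-, the median length of distinct deletions of 11 bp or more was 104.5 bp in amplicon 1 and at most 64.5 bp in the other amplicons, a gap of 0.860 of the range, past the 95% critical value of Dixon's ratio. The value rests on 4 distinct deletions.

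The first pattern weighed is the excess of deletions of 11 bp or more in Atm-/-. The read length and whether mates were joined are not given in the sources used here, so wrongly joined reads are an assumption. If they place ends in the middle of the amplicon in reads with substitutions, they are not the whole cause, since without both kinds of read the excess was still 6.08-fold (exact permutation p = 0.0039). The 41-bp stretch was set from these data, and joining errors that leave ends elsewhere and no substitution were not tested. Copying between repeats during PCR would leave little excess among deletions with 0 or 1 bp of microhomology, and the excess there was 9.94-fold (exact permutation p = 0.0039), against 1.94-fold for 4 bp or more (exact permutation p = 0.0195). The submission set cannot be told apart from the genotype, because the first set holds all 4 Atm-/- libraries and no others. Among the other 3 genotypes the second set lay 1.65-fold above the third and the fourth in reads without substitutions (exact permutation p = 0.185). With middle ends also left out it lay 1.11-fold above them (exact permutation p = 0.790). The second set holds no Spo11-/- library, so these folds mix set with genotype too. Loss of ATM may therefore raise the number of deletions, as a hypothesis that stays open to a set effect and to the unknown number of genomes and share of cell types in each PCR.

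The next pattern is that ends of Atm-/- deletions recurred at like positions in different amplicons. The test used the 106 distinct deletions of reads without substitutions and without ends in the middle of the amplicon, and left out pairs of identical deletions. On the chromosome, 299 pairs of ends lay within 2 bp of each other, against 173 ± 14.4 (SD) after moving each end by up to 15 bp (permutation p = 0.0001, the smallest that 10000 draws can give). This count describes the pattern and supports no cause of it. In all counts of this paragraph, moved ends were not placed left-most again and could enter the stretch left out, which may lower the counts after moving. Counted in the same way, the other 3 genotypes together had 30 pairs over 58 deletions, each counted once per amplicon, against 18.25 ± 4.204 (SD) after moving (permutation p = 0.0093), and Spo11-/- alone 6 pairs over 22, against 2.63 ± 1.55 (permutation p = 0.0459). Atm+/- alone had 2 pairs over 26 and Atm+/+ 1 over 15 (permutation p = 0.619 and 0.830). With so few pairs these counts do not decide whether recurring ends are particular to Atm-/-. In read position 83 pairs of Atm-/- ends lay within 2 bp, against 64.6 ± 8.03 (permutation p = 0.0187), so ends set by the position in the read are not excluded for part of the pattern. Sequence prone to deletion in every genotype stays open: 25.4% of the other genotypes' 63 deletions began within 2 bp of an Atm-/- deletion of another amplicon, against 31.0% ± 4.53 (SD) after moving their starts (permutation p = 0.922 for a higher share), which does not decide it. Preferred break positions in Atm-/- were not tested apart from the pattern, and no cause is put forward.

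The last pattern is that some deletions were found in several genotypes. Of the 10 deletions found in 2 or more genotypes in reads without substitutions, 8 (80%) had at least 4 bp of microhomology, against 23 of 198 (11.6%) of those found in 1 genotype (Fisher's exact test, p = 3.77e-06). The 10 may not be independent: those that start at 33765176, 33765180 and 33765345 all end at 33765366. The test also mixes sharing with genotype. In these reads 12.7% of Atm-/- deletions had at least 4 bp, against 37.5% in the other 3 genotypes. Spo11-/- held 4 of the 10, and 33765369 to 33765413 (45 bp, 6 bp of microhomology) was found in all 4 genotypes. These values are consistent with copying between short repeats independent of SPO11, in the PCR or in the animals. No test here separates PCR from events in the animals, and carry-over between libraries was not tested.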

How the results depend on the processing

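Settings chosen after seeing the data are those that leave out reads with an undetermined base, ends in the middle of the amplicon, or the second submission set. The excess of distinct deletions of 11 bp or more in Atm-/- kept its direction and passed the test in 19 of 19 alternatives (log2 2.02 to 3.61, exact permutation p 0.000549 to 0.0156). Of the alternative values of all 10 results, 157 kept direction and side of the threshold, 11 turned direction and 6 came to pass the test. A call was lost in 7, of which 2 are among those that turned direction.

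Reads with a deletion in Atm-/- were at log2 3.09 to 3.62 with 1 amplicon left out, where leaving out amplicon 3 or 4 gave an exact permutation p of 0.0625, and at 2.00 without reads that hold an undetermined base. The difference in median length was 3.92 bp in reads without substitutions, 17.5 bp without undetermined bases, -20.9 bp with middle ends also left out, and -12.9 bp without the second set and reads with substitutions. The microhomology difference was 0.28 points for private deletions, -22.0 in reads without substitutions (exact permutation p = 0.0391), -27.0 with middle ends also left out (again 0.0391), and -26.3 without the second set and reads with substitutions, where it did not pass the test (exact permutation p = 0.0741). Deletions of 2 to 10 bp were at -0.23 in reads without substitutions and -0.29 without the second set too (exact permutation p = 0.037). Spo11-/- against Atm+/+ and Atm+/- turned to 0.18 for distinct deletions and 0.061 for reads without middle ends, and to 0.014 without the second set and reads with substitutions. Atm+/- against Atm+/+ turned to -0.55 with at least 2 reads per deletion and -0.14 with at least 5. With the set as a block, in the fit that also used the Spo11-/- libraries, it was -0.031. It ranged from -0.52 to 1.12 with 1 amplicon left out. The cause of these changes was not tested beyond the reads each setting removes.

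Without the replicate block the pairs Atm-/- against Atm+/+ (log2 2.41) and against Spo11-/- (3.61) reached an exact permutation p of 0.0286, since more assignments are possible; it changed no other call. The planned denominator of reads with a 1-bp deletion was not run, because such deletions were not analysed here, and at least 2 or 5 reads per deletion gave no value for median length and microhomology. The comparisons among the other 3 genotypes rest on 88 distinct deletions in 12 libraries in reads without substitutions.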

Other observations

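The 10-bp bin below was chosen after seeing the data; the test of a length period was written before its result was seen. In reads without substitutions and without ends in the middle of the amplicon, the first deleted base of 19 of 106 Atm-/- deletions (17.9%) lay between 33765000 and 33765009, and that of 1 of 63 (1.59%) in the other 3 genotypes. The bin was picked because it holds the most Atm-/- deletions, so its difference between genotypes was not tested. The bin held 4 of 26 Atm-/- deletions in amplicon 1, 5 of 22 in amplicon 2, 9 of 36 in amplicon 3 and 1 of 22 in amplicon 4. It lies at read positions 313 to 322, 204 to 213, 86 to 95 and 18 to 27 of these amplicons.

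In the same reads the pooled median length of the deletions of 11 bp or more was 59.5 bp over the 106 Atm-/- deletions (upper quartile 119.75 bp) and 58 bp over the 63 others (upper quartile 112.5 bp). The mean of the library medians was 57.1 bp in Atm-/- and 78 bp in the other 12 libraries, a difference of -20.9 bp that did not pass the test (exact permutation p = 0.363). The ratio of Atm-/- to the other 3 genotypes varied between 50-bp windows in these reads. At 33764888 to 33764937, 2 Atm-/- deletions gave 0.30 per 1e6 reads and the other 3 genotypes 0.30, a ratio of 1.00. At 33764988 to 33765037 the ratio was 19.0, and at 33765388 to 33765437 it was 7.41. The windows next to that one had ratios of 3.05 and 2.62. Windows covered by 1 or 2 amplicons, as these last 3 and the first named are, were not tested.

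A hypothesis was that the lengths of Atm-/- deletions repeat with the turn of the DNA helix, a period between 10 and 11 bp. For the 79 deletions of 11 to 120 bp the vector strength at that period was 0.159, against a mean of 0.100 after moving each length by up to 15 bp (permutation p = 0.139). A period was not detected with this number of deletions.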
